A study of Saccharomyces cerevisiae with 3 samples.

How the data were processed

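The series holds 3 two-colour arrays, each a direct comparison of RNA from arsenite-treated and untreated wild-type yeast, per the labels. The dyes were exchanged on replicate 3, per the labels. The deposited table holds 1 value for each of 13056 spots on each array, with 0 missing values. The deposited values were read as log2 ratios of the 2 channels made by the authors. The base is not stated: base 10 would mean ratios beyond the reach of an array and was excluded, whereas a natural logarithm was not excluded, in which case every log2 ratio printed here would be larger by a constant factor, the folds and the counts at 2-fold would be larger too, and no test against 0 would change. The scanner, the background correction and the normalization that the authors used are not given in the sources used here. The columns were not all centred on 0. The column of replicate 3 was taken as not yet turned for its exchanged dyes, from its negative correlation with the other arrays. An already turned column in which dye bias outweighed the treatment would correlate negatively too. The direction was taken as Cy5 over Cy3, from the dyes in the labels and from titles that put the treated cells first. The number of arrays limits the precision, and the table holds no intensities, so signal over background is unknown.

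Spots were named through the platform annotation supplied with the series. It gives 1 gene symbol for 11138 spots, several for 0 and none for 1918. The named spots stand for 5539 genes, of which 5510 have 2 spots, 28 have 4 and 1 has 6. Of the gene IDs, 5534 matched the RefSeq table of assembly R64, 5 did not, and 0 symbols were updated. That table was used for names and for which genes neighbour each other, and no coordinates are given because the files name no genome build. Duplicate spots correlated with r = 0.939, 0.927 and 0.936 on replicates 1, 2 and 3, over 5569 pairs. The SD of a single spot, from duplicates, was 0.19, 0.22 and 0.20 on the log2 scale. Of the 29 genes with more than 2 spots, 0 had spot pairs that differed by over 1. Genes with close paralogs, among them the ribosomal protein pairs, the aryl-alcohol dehydrogenase, hexose transporter, histone and SSA chaperone genes, may share hybridisation, and the files do not describe the probes.

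The spots of a gene were averaged on each array, replicate 3 was multiplied by -1, and the mean over arrays was tested against 0 with lmFit and eBayes of limma 3.58.1 in R 4.3.3. P-values were two-sided and adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. As deposited, the prior degrees of freedom were infinite, so that every gene had the same standard error of 0.290; with each array centred they were 10.8, beside 2 residual degrees of freedom. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

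Gene lists were tested with limma's camera, which compares a list with all other genes, at a preset inter-gene correlation of 0.01, with adjustment over 25 lists. The lists cover arsenic detoxification, sulfate assimilation with methionine and cysteine synthesis, glutathione, thioredoxin and oxidative defence, aryl-alcohol dehydrogenases, heat shock proteins, the proteasome, general stress with trehalose and glycogen, osmotic targets of Hog1, iron uptake, multidrug and hexose transporters, glycolysis, other amino acids, cytosolic ribosomal proteins, ribosome biogenesis, RNA polymerases I and III, histones, the cell cycle, ergosterol, the respiratory chain, a-cell, alpha-cell and meiosis genes, and regulators. Some genes stand in more than 1 list. A few listed genes, among them AAD16 and NOP10, had no named spot and were not tested. Among lists that passed, the median had the direction of the test on all 3 arrays except for iron uptake, the cell cycle, a-cell and meiosis genes, each with 1 array on the other side of 0. Against the median over all spots of replicate 2 (0.54), iron uptake (0.04), the cell cycle (0.0006) and a-cell genes (0.14) lay lower there, in the direction of the test. Meiosis genes on replicate 3 (-0.16) lay against the test by this measure too, since that array had -0.12 once turned. With the correlation estimated from the residuals, which have 2 degrees of freedom, 0 lists passed in either direction.

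The lists, the test, the rule for naming genes and most alternatives were fixed before the data were examined. The rule named the 8 genes with the largest rise and the 8 with the largest fall among those past the threshold with 1 sign on all 3 arrays. It also named all arsenic detoxification genes and regulators and, for each list that passed or had at least 3 members past the threshold, up to 3 members with the largest change in the main direction. Members that ran against their list, the glycolysis genes, the alpha-cell gene STE3, GSH1, GPD1 and AAD4, were named in addition after their values were seen.

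The alternatives tried were centring each array on its median, centring with scaling, a minimum of 2 arrays per gene, a dye effect in the fit, the median over spots, leaving out each array, a 2-fold minimum, robust eBayes, an estimated correlation, the rotation test fry, camera on ranks and Spearman's correlation. Centring within 48 runs of consecutive spots per array and the counts of list members with each array left out were added after the data were examined. The steps were tested on simulated data of 5539 genes and 3 arrays, arsenite over untreated, with 200 genes changed. Of simulated log2 changes of 0.5, 1 and 2, the fit as deposited recovered 2.99%, 52.2% and 100%, with 1 false call (0.962% of calls), and the centred fit 7.46%, 77.6% and 100%, with 3 false calls (2.38%). A simulated list of 20 genes shifted by 0.5 had camera p = 3.06e-11 with the preset and p = 0.158 with the estimated correlation. Of 200 unshifted lists, 0% fell under 0.05 with either. These lists were drawn only from genes without a simulated change, while the changed genes stayed among the genes compared with. The 0% is therefore not a false-positive rate for lists drawn from all genes. The simulated genes were independent of each other. In the real lists the estimated correlation ran from -0.239 (arsenic detoxification) to 0.895 (meiosis). The simulation therefore does not show how often a list of correlated genes passes falsely at the preset 0.01.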

Results

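Transcript ratios were measured in wild-type Saccharomyces cerevisiae, budding yeast, exposed to 0.2 mM arsenite, the trivalent form of arsenic, for 1 h. On each of 3 arrays the RNA of treated cells was hybridised together with that of untreated cells, so each array gives 1 treated-to-untreated ratio per spot. The treated RNA carried the dye Cy5 on replicates 1 and 2 and Cy3 on replicate 3, per the labels. The deposited medians over all spots were -0.07, 0.54 and 0.12 for replicates 1, 2 and 3. Over all spots, replicate 3 as deposited correlated negatively with replicate 1 (r = -0.782) and with replicate 2 (r = -0.613), whereas replicates 1 and 2 correlated positively (r = 0.784). The third array was therefore turned. This takes the effect of treatment to outweigh dye bias, since the sources do not state whether that column had been turned already. The base of the deposited logarithm is not stated and was read as 2; were it a natural logarithm, the log2 ratios, the folds and the counts at 2-fold below would be larger. All values below are log2 ratios of arsenite-treated over untreated cells, given as mean ± SD over the 3 arrays. That direction is likely rather than stated, since it takes the deposited ratio as Cy5 over Cy3, and every sign below would be opposite if the ratio were Cy3 over Cy5. After turning, Pearson's r across genes was 0.823 for replicates 1 and 2, 0.842 for replicates 1 and 3 and 0.679 for replicates 2 and 3. Genes are not independent replicates, so these values describe only how the arrays repeat.

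The comparison asks which transcripts differ in level between cells exposed to arsenite and unexposed cells of the same strain. The 8 largest rises included genes of oxidative defence, of glutathione conjugation and of the general stress response, and ribosomal protein genes made up most of the 8 largest falls. OYE3, a NADPH-dependent oxidoreductase of the old yellow enzyme family, rose 30.4-fold (4.93 ± 0.91, n = 3, limma adjusted p = 4.22e-60). That value uses the standard error common to all genes, and with each array centred the limma adjusted p of OYE3 was 6.12e-08. OSI1 rose 27.5-fold (4.78 ± 0.38), HSP12, a small heat shock protein, rose 24.7-fold (4.63 ± 0.29) and GTT2, a glutathione S-transferase, rose 21.2-fold (4.41 ± 0.31). Next came GRE2, a methylglyoxal reductase (4.28 ± 0.13), PRX1, the mitochondrial peroxiredoxin (4.13 ± 0.47), AAD14 of the aryl-alcohol dehydrogenase family (3.93 ± 0.43) and ECM4, a glutathione transferase (3.83 ± 0.61). The largest fall was that of URA1, dihydroorotate dehydrogenase of pyrimidine synthesis (-2.52 ± 0.60). OLE1, the fatty acid desaturase, had -2.30 ± 0.42 and UTR2, a cell wall transglycosylase, -2.24 ± 0.45. The other large falls were in the ribosomal protein genes RPL22A (-2.42 ± 0.34), RPS0B (-2.32 ± 0.43), RPL9B (-2.29 ± 0.34), RPL6B (-2.26 ± 0.40) and RPS17A (-2.25 ± 0.38). All 16 of these genes had 1 sign on all 3 arrays and passed the test with any 1 array left out.

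**Figure D1:**
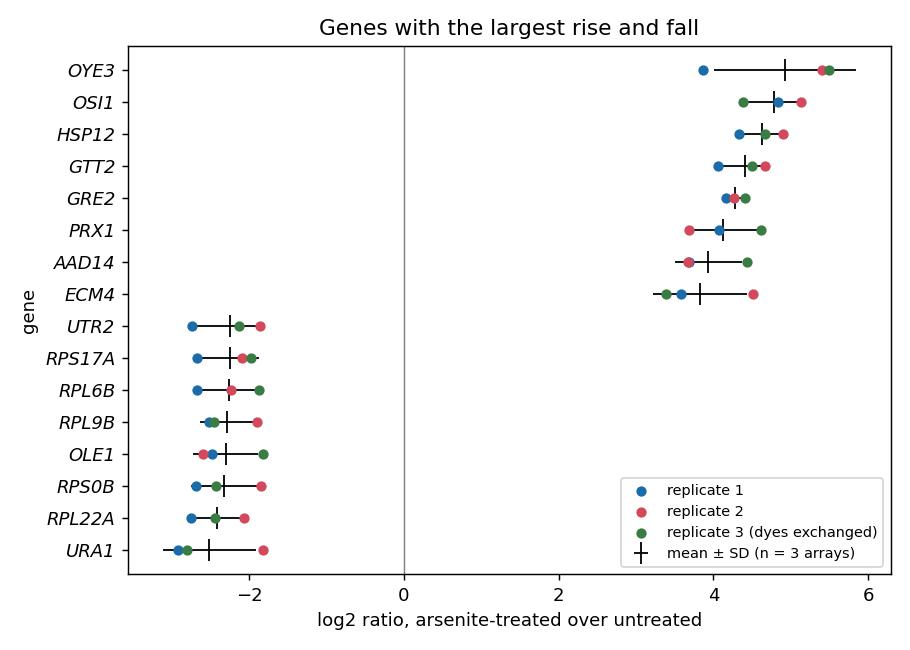
Log2 ratio of arsenite-treated over untreated cells (horizontal axis) for the 8 genes with the largest rise and the 8 with the largest fall. Points are the 3 arrays and bars the mean ± SD; the means run from 4.93 for OYE3 to -2.52 for URA1, and every point lies on the same side of 0 as its mean.

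Over 5539 genes tested, 606 rose and 603 fell at an adjusted p threshold of 0.05, and 4330 did not pass. A change of at least 2-fold was reached by 347 of the genes that rose and 387 of those that fell. Of all genes, 48.1% had 1 sign on all 3 arrays, and 1178 of the genes past the test did. Independent and even signs would give 25%. That is not the chance level here, because replicate 3 was turned by its correlation with the other arrays and the arrays differ in offset. Replicate 2 lay above the other arrays, with a median ratio over all spots of 0.54, and the counts differed when the arrays were centred. With each array centred on its median, 805 genes rose and 1004 fell, which included 600 of the 606 and all 603. Without replicate 1 the counts were 261 and 224, without replicate 2 they were 699 and 1318, and without replicate 3 they were 456 and 349. These p-values rest on the spread between these 3 arrays only, since the labels do not say whether the arrays came from separate cultures. An exact sign test on 3 arrays cannot go below p = 0.25. As deposited, every gene had the same standard error of 0.290, which includes the offset of replicate 2. A p-value therefore does not reflect the SD printed beside it. A call can also be lost with an array left out while the mean of the gene hardly changes.

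Among the arsenic detoxification genes, those for the reductase, the exporter and the vacuolar pump rose. ARR2, the arsenate reductase, rose 12.9-fold (3.69 ± 0.07) and ARR3, the plasma membrane exporter of arsenite, rose 3.78-fold (1.92 ± 0.38). YCF1, the vacuolar pump for glutathione conjugates, rose 2.06-fold (1.04 ± 0.14, adjusted p = 0.00262), a call that was lost without replicate 1 (adjusted p = 0.135) or replicate 3 (0.0618). The mean of YCF1 was 1.03 and 0.98 in these settings, so its ratio hardly moved, and its limma adjusted p was 0.00366 with each array centred. ARR1, the transcription factor encoded beside ARR2 and ARR3, had -0.0034 ± 0.30, and FPS1, the glycerol channel through which arsenite enters, had -0.37 ± 0.20 (adjusted p = 0.412); neither passed, though FPS1 did after centring within runs of spots (adjusted p = 0.0360). Of the 5 measured genes of this list, 3 rose, also when adjusted over the list alone, and the list median was 1.04 (camera adjusted p = 0.000624). The list call was lost on ranks (adjusted p = 0.124) and with an estimated correlation (adjusted p = 0.296), the latter as for every other list that passed.

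Transcripts of sulfur assimilation and of methionine and cysteine synthesis rose in large part. Of 28 measured genes, 16 rose and 2 fell (18 and 2 adjusted over the list alone), with a list median of 1.06 (adjusted p = 1.05e-09, and adjusted p = 0.296 with an estimated correlation). The largest rises were those of MET14, adenylylsulfate kinase (2.61 ± 0.22), STR3, a cystathionine beta-lyase (2.49 ± 0.33), and MET16, which reduces phosphoadenylylsulfate (2.46 ± 0.23). The 2 genes that fell were SAH1, S-adenosylhomocysteine hydrolase (-1.25 ± 0.32), and MET13, a methylenetetrahydrofolate reductase (-0.79 ± 0.60). Without replicate 1, 0 genes of this list fell, and without replicate 3, 1 did. Of 18 genes of glutathione metabolism, 12 rose and 0 fell (14 adjusted over the list alone), with a median of 1.04 (adjusted p = 1.31e-08, and adjusted p = 0.321 with an estimated correlation). GTT2 led this list, followed by GRX2, a glutaredoxin (2.52 ± 0.14), and HYR1, a thiol peroxidase (1.53 ± 0.37). GSH1, the first enzyme of glutathione synthesis, rose by 1.38 ± 0.27. Without replicate 1, 7 of the glutathione genes passed.

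The oxidative defence and aryl-alcohol dehydrogenase lists had the highest medians. Of 23 genes of the thioredoxin system and oxidative stress defence, 20 rose and 0 fell (20 and 1 adjusted over the list alone), with a median of 1.69 (adjusted p = 4.58e-23, and adjusted p = 0.296 with an estimated correlation). OYE3, GRE2 and PRX1 rose most among them, and without replicate 1, 13 genes of the list rose. Without replicate 2, 20 rose and 1 fell. All 6 measured aryl-alcohol dehydrogenase genes rose, by a median of 3.54 (adjusted p = 4.58e-23, and adjusted p = 0.227 with an estimated correlation), also when adjusted over the list alone. AAD14, AAD15 (3.63 ± 0.30) and AAD10 (3.57 ± 0.27) rose most, and AAD4 least (0.87 ± 0.13). Without replicate 1, and likewise without replicate 3, 5 of the 6 rose. These genes are close paralogs, and the files do not show how far their spots cross-hybridise.

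Proteasome genes moved almost as a block: 27 of 32 rose and 1 fell (29 and 1 adjusted over the list alone), with a median of 1.12 (adjusted p = 1.57e-11, and adjusted p = 0.296 with an estimated correlation). The 20S core subunits PRE8 (1.72 ± 0.24), PRE1 (1.71 ± 0.48) and PRE3 (1.68 ± 0.16) rose most, and the lid subunit RPN9 fell (-0.87 ± 0.29). Without replicate 1, 13 proteasome genes rose and 0 fell, and without replicate 3, 26 rose and 0 fell. Of 26 heat shock proteins and chaperones, 10 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.61 (adjusted p = 6.58e-07, and adjusted p = 0.480 with an estimated correlation). HSP12, HSP104, the disaggregase (2.50 ± 0.09), and BTN2 (2.36 ± 0.55) rose most, and the small heat shock protein HSP42 fell (-0.97 ± 0.91). HSP42 was not among the genes past the test without replicate 1 or without replicate 3, when 0 of the list fell, and without replicate 2, 2 fell.

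General stress genes and genes of trehalose and glycogen metabolism rose together, with 15 of 22 higher and 0 lower (17 and 0 adjusted over the list alone) and a median of 1.18 (adjusted p = 5.95e-18, and adjusted p = 0.296 with an estimated correlation). HSP12, YGP1, a cell wall glycoprotein (3.50 ± 0.57), and TFS1, an inhibitor of carboxypeptidase Y (3.16 ± 0.45), led the list. Of 13 osmotic stress targets of the MAP kinase Hog1, 7 rose and 1 fell, also when adjusted over the list alone, with a median of 0.82 (adjusted p = 0.000624, and adjusted p = 0.321 with an estimated correlation). GRE2, GCY1 (2.02 ± 0.47) and HOR7 (1.43 ± 0.33) rose most. The glycerol synthesis enzyme GPD1 rose by 1.21 ± 0.29, whereas GPP1, the phosphatase that follows it, fell (-1.02 ± 0.48). Leaving out replicate 1 gave 4 Hog1 targets that rose and 0 that fell, replicate 2 gave 8 and 2, and replicate 3 gave 6 and 0.

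Ribosomal protein genes fell together. Of 132 measured genes for cytosolic ribosomal proteins, 125 fell and 1 rose, also when adjusted over the list alone, and the list median was -1.78 (adjusted p = 8.03e-81, and adjusted p = 0.296 with an estimated correlation). The list medians on replicates 1, 2 and 3 were -1.91, -1.41 and -1.87. RPS30A was the gene that rose (0.77 ± 0.46, adjusted p = 0.0399), and no gene of the list rose without replicate 1 or without replicate 3. The 6 that did not pass were RPL43B (0.52), RPS19A (0.39), RPL41B (0.12), RPL10 (-0.39), RPL40A (-0.54) and RPL4B (-0.56); these and RPS30A were picked out after their values were seen. Of 46 ribosome biogenesis genes, 37 fell and 0 rose (40 and 0 adjusted over the list alone), with a median of -1.16 (adjusted p = 4.54e-20, and adjusted p = 0.393 with an estimated correlation). The snoRNP proteins NOP56 (-1.97 ± 0.51) and CBF5 (-1.93 ± 0.09) and the nucleolar protein NSR1 (-1.76 ± 0.57) fell most. Without replicate 1, 18 of them fell, and without replicate 3, 23 fell. Of 20 subunits of RNA polymerases I and III, 9 fell and 1 rose (10 and 1 adjusted over the list alone), with a median of -0.62 (adjusted p = 5.50e-05, and adjusted p = 0.607 with an estimated correlation). RPA49 (-1.60 ± 0.68), RPA135 (-1.52 ± 0.36) and RPA43 (-1.47 ± 0.60), all of polymerase I, fell most, and RPA14 rose (0.91 ± 0.82). Without replicate 1, 4 polymerase subunits fell and 0 rose, and without replicate 2, 16 fell and 0 rose.

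**Figure D2:**
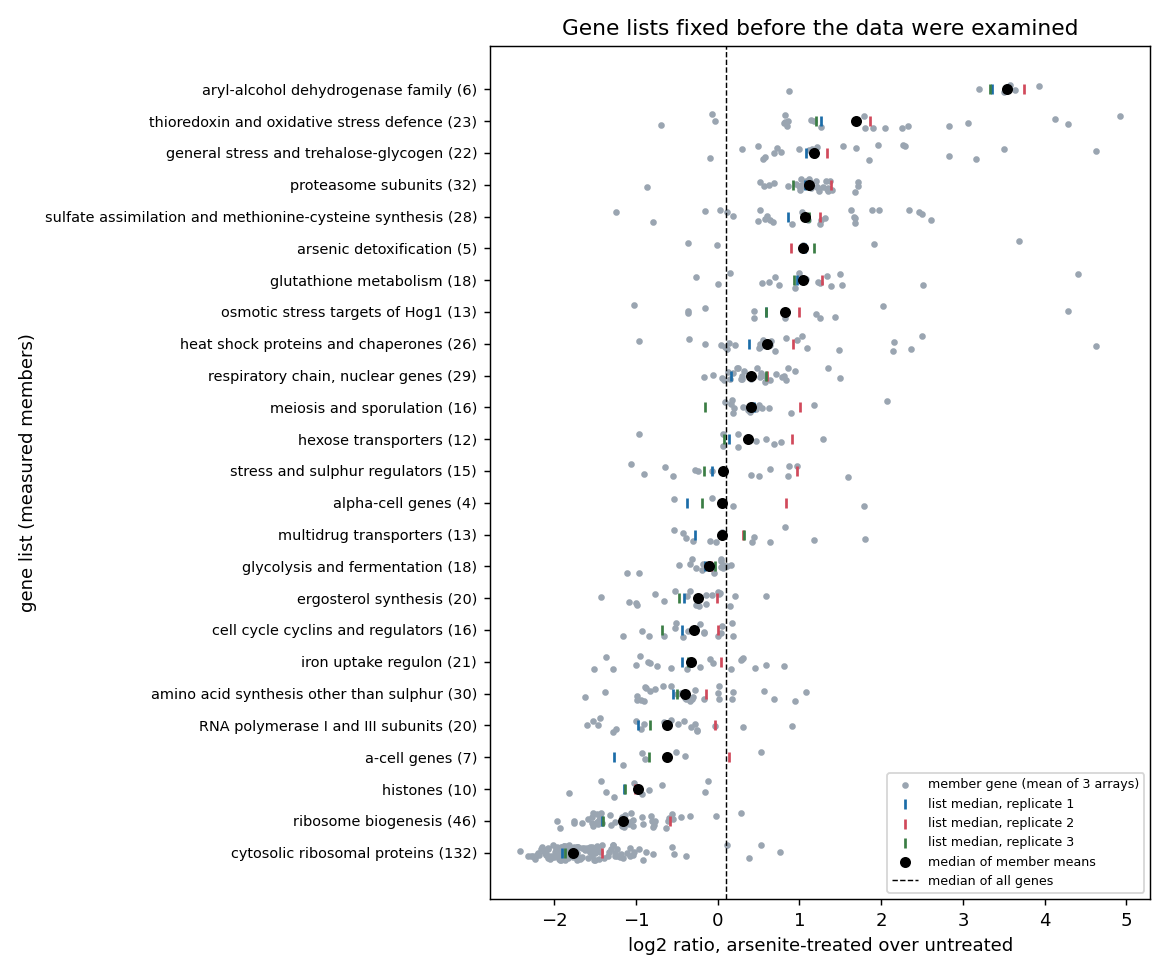
Log2 ratio of arsenite-treated over untreated cells (horizontal axis) for the members of 25 gene lists (vertical axis, number of measured members in brackets). Grey points are member genes, coloured ticks the list median on each array, black points the median of the member means and the dashed line the median of all genes (0.098); list medians run from 3.54 for the aryl-alcohol dehydrogenase family to -1.78 for cytosolic ribosomal proteins.

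Histone genes fell: 7 of 10 did and 0 rose (8 and 0 adjusted over the list alone), with a median of -0.97 (adjusted p = 3.81e-05, and adjusted p = 0.296 with an estimated correlation). HTA2, for histone H2A (-1.82 ± 0.19), and the histone H4 genes HHF2 (-1.42 ± 0.11) and HHF1 (-1.36 ± 0.12) fell most. Without replicate 1, 3 histone genes fell, and without replicate 3, 4 did. Of 16 cyclins and cell cycle regulators, 3 fell and 0 rose, also when adjusted over the list alone, with a median of -0.29 (adjusted p = 0.0416, and adjusted p = 0.607 with an estimated correlation). These were FAR1, an inhibitor of cyclin-dependent kinase (-1.16 ± 0.76), CLB1, a mitotic cyclin (-0.93 ± 0.43), and SWI5, a transcription factor of the M/G1 transition (-0.83 ± 0.61). None of the 3 passed without replicate 1 (adjusted p = 0.242, 0.224 and 0.251) or without replicate 3 (0.0531, 0.203 and 0.406), and without replicate 2, 8 cell cycle genes fell. With each array centred, 6 fell and 0 rose. The list itself did not pass without replicate 2 (adjusted p = 0.0536) or replicate 3 (0.0601), and its medians on replicates 1 and 3 were -0.44 and -0.68, with that of replicate 2 just above 0.

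Markers of mating type and of sporulation were included as genes of cell states that a yeast culture could hold. The sample titles give no mating type, so the a-cell or the alpha-cell genes may be those of the strain itself. Of 7 a-cell genes, 3 fell and 0 rose, also when adjusted over the list alone, with a median of -0.63 (adjusted p = 0.0307, and adjusted p = 0.607 with an estimated correlation). They were MFA2, an a-factor gene (-1.15 ± 0.77), STE2, the alpha-factor receptor (-0.93 ± 0.94), and STE6, the a-factor exporter (-0.89 ± 0.67), and STE2 alone among the genes past the test that the naming rule picked did not have 1 sign on all 3 arrays. STE2 had 0.14 on replicate 2, below the median of that array over all spots (0.54). The list medians of the a-cell genes were -1.27, 0.14 and -0.84 on replicates 1, 2 and 3, and the list did not pass without replicate 1 (adjusted p = 0.0845). Without replicate 1, MFA2, STE2 and STE6 had adjusted p = 0.385, 0.367 and 0.204, and 0 of the list fell; without replicate 2, 6 fell, and without replicate 3, 1 fell and STE2 and STE6 had adjusted p = 0.334 and 0.381. Of 4 alpha-cell genes, STE3, the a-factor receptor, rose (1.79 ± 0.90), 3 did not pass, also when adjusted over the list alone, and the list did not pass (median 0.05, adjusted p = 0.475, and adjusted p = 0.721 with an estimated correlation). Without replicate 2, 1 alpha-cell gene rose and 1 fell. Of 16 meiosis and sporulation genes, 3 rose and 0 fell, also when adjusted over the list alone, with a median of 0.41 (adjusted p = 0.0239, and adjusted p = 0.671 with an estimated correlation). IME2, a meiotic protein kinase (2.07 ± 0.86), DIT1, of spore wall formation (1.17 ± 0.76), and HOP1, of the synaptonemal complex (0.89 ± 0.63), rose, HOP1 not without replicate 1 (adjusted p = 0.193) or with a dye effect in the fit (0.101). The meiosis list had medians of 0.45, 1.01 and -0.16 on replicates 1, 2 and 3, and did not pass without replicate 2 (adjusted p = 0.133) or with a dye effect in the fit (0.0665).

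Genes of the iron uptake regulon were lower in part: 8 of 21 fell and 1 rose, also when adjusted over the list alone, with a median of -0.33 (adjusted p = 0.0239, and adjusted p = 0.607 with an estimated correlation). FET3, the multicopper ferroxidase (-1.51 ± 0.60), FIT2, a cell wall mannoprotein (-1.36 ± 0.39), and FTR1, the permease that works with FET3 (-1.29 ± 0.39), fell, and the siderophore transporter ARN1 rose (0.81). FIT2 and FTR1 did not pass without replicate 1 (adjusted p = 0.0834 and 0.110). The numbers of iron genes that fell were 1, 10 and 4 without replicate 1, 2 and 3, and 0 rose in each case. The list medians of the 3 arrays were -0.44, 0.04 and -0.36.

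Among transporters of other kinds, the changes were few. Of 13 multidrug transporters, 3 rose and 0 fell, also when adjusted over the list alone, and the list did not pass (adjusted p = 0.356, and adjusted p = 0.721 with an estimated correlation). ATR1 (1.80 ± 0.54) and FLR1 (1.18 ± 0.18), which belong to the oxidative defence list too, and YOR1 (0.82 ± 0.60) rose. FLR1 did not pass without replicate 1 (adjusted p = 0.0839), nor YOR1 without replicate 1 (0.496) or with a dye effect in the fit (0.178). Without replicate 1, 1 multidrug transporter rose, and without replicate 2, 4 rose and 3 fell. With each array centred, 4 multidrug transporters rose and 2 fell. Of 12 hexose transporters, 2 rose and 1 fell, also when adjusted over the list alone, and the list did not pass (median 0.37, adjusted p = 0.228, and adjusted p = 0.721 with an estimated correlation). HXT11 (1.29 ± 0.16) and HXT7 (0.78 ± 0.41) rose and HXT2 fell (-0.97 ± 0.51), HXT7 not without replicate 1 (adjusted p = 0.232) or replicate 3 (0.376). In each of these 2 settings 1 hexose transporter rose and 0 fell, and without replicate 2, 3 rose and 1 fell. With each array centred, 4 hexose transporters rose and 1 fell.

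The lists of glycolysis, of other amino acids and of ergosterol all leaned downward, and that of glycolysis did not pass. Of 18 glycolytic and fermentation genes, 2 fell and 0 rose, also when adjusted over the list alone, and the list did not pass (median -0.10, adjusted p = 0.176, and adjusted p = 0.642 with an estimated correlation), though it did in the test on ranks (adjusted p = 0.0309). The 2 were PFK2 (-1.11 ± 0.25) and PFK1 (-0.96), the subunits of phosphofructokinase, and without replicate 1 neither passed. Of 30 genes of amino acid synthesis outside the sulfur pathway, 10 fell and 2 rose (11 and 3 adjusted over the list alone), with a median of -0.40 (adjusted p = 0.00678, and adjusted p = 0.607 with an estimated correlation). ILV5, of branched-chain amino acids (-1.62 ± 0.17), HIS1 (-1.38 ± 0.44) and ARO4 (-0.99 ± 0.53) fell, and LYS1 (1.08) and SER33 (0.94) rose. ARO4 did not pass without replicate 1 (adjusted p = 0.275) or replicate 3 (0.129). Only 2 of these genes fell without replicate 1, when 0 rose, and 2 without replicate 3. Of 20 ergosterol genes, 5 fell and 0 rose, also when adjusted over the list alone, with a median of -0.25 (adjusted p = 0.0241, and adjusted p = 0.607 with an estimated correlation). ERG3 (-1.43 ± 0.28), HMG1, a hydroxymethylglutaryl-CoA reductase (-1.09 ± 0.29), and ERG11 (-0.998 ± 0.55) fell most. HMG1 and ERG11 did not pass without replicate 1 (adjusted p = 0.113 and 0.283), nor ERG11 without replicate 3 (0.119), and the numbers of ergosterol genes that fell were 1, 9 and 2 without replicate 1, 2 and 3.

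Nuclear genes of the respiratory chain rose in part, with 7 of 29 higher and 0 lower (8 and 0 adjusted over the list alone) and a median of 0.41 (adjusted p = 0.0103, and adjusted p = 0.607 with an estimated correlation). The succinate dehydrogenase subunits SDH1 (1.49 ± 0.30) and SDH2 (1.35 ± 0.37) and CYC1, cytochrome c (0.94 ± 0.34), rose most. CYC1 did not pass without replicate 1 (adjusted p = 0.136), and the list did not pass without replicate 3 (0.0603). Without replicate 1, 2 respiratory genes rose, and without replicate 3, 4 did.

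Of 15 transcriptional and signalling regulators of stress and sulfur metabolism, 4 rose and 2 fell, also when adjusted over the list alone, and the list did not pass (median 0.07, adjusted p = 0.694, and adjusted p = 0.912 with an estimated correlation). RPN4, the activator of proteasome genes, rose by 1.60 ± 0.50, and MET30, the ubiquitin ligase subunit that restrains MET4, by 0.97 ± 0.66. YAP1, the activator of oxidative defence genes (0.88 ± 0.45, adjusted p = 0.0149), and MET28, a cofactor of MET4 (0.86 ± 0.42, adjusted p = 0.0177), rose. GCN4, the activator of amino acid synthesis (-1.06 ± 0.44, adjusted p = 0.00228), and MET32, a DNA-binding partner of MET4 (-0.90 ± 0.73, adjusted p = 0.0124), fell. RPN4 passed with any 1 array left out. Without replicate 1 the adjusted p was 0.1000 for MET30, 0.142 for YAP1, 0.147 for MET28, 0.162 for GCN4 and 0.360 for MET32. Without replicate 3 it was 0.0564 for YAP1, 0.0752 for MET28, 0.105 for GCN4 and 0.286 for MET32. With a dye effect in the fit it was 0.0521 for MET30, 0.0651 for YAP1 and 0.0655 for MET28. The 9 that did not pass were SKN7 (-0.65), MET4 (0.41), MET31 (-0.54), CBF1 (-0.27), HSF1 (0.63), MSN2 (-0.06), MSN4 (0.51), HOG1 (-0.25) and AFT1 (0.07). SKN7, MET31 and CBF1 passed without replicate 2 (adjusted p = 0.000166, 0.00836 and 0.0137), and HSF1 without replicate 3 (0.0440). SKN7 and MET31 also passed with each array centred (adjusted p = 0.00687 and 0.0182). With centring within runs of spots the adjusted p was 0.0290 for SKN7, 0.0219 for MET31, 0.0434 for HSF1 and 0.0431 for MSN4. The numbers that rose and fell were 1 and 0 without replicate 1, 4 and 5 without replicate 2, and 3 and 0 without replicate 3. For this list and those of multidrug transporters and alpha-cell genes the test leaned upward, and the mean was above 0, while the list median minus that of all genes was -0.03, -0.05 and -0.04. The medians on replicates 1, 2 and 3 were -0.07, 0.97 and -0.16 for the regulators, -0.28, 0.31 and 0.32 for multidrug transporters and -0.37, 0.84 and -0.20 for alpha-cell genes.

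**Figure D3:**
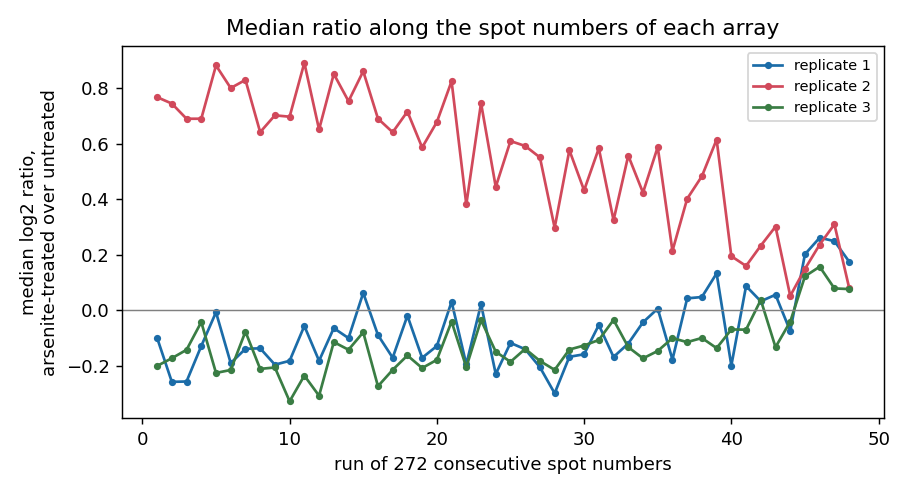
Median log2 ratio of arsenite-treated over untreated cells (vertical axis) in each of 48 runs of consecutive spot numbers (horizontal axis) on the 3 arrays, 1 line per array. Replicate 2 falls from a median of 0.76 over its first 8 runs to 0.21 over its last 8, while replicate 1 goes from -0.16 to 0.13 and replicate 3 from -0.17 to 0.03.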

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

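Centring within runs of spots and the recounts of list members with an array left out were chosen after the results were seen. The number of genes that fell was 1004 with each array centred, 991 with scaling as well and 1174 with centring within runs, where 910 rose. With a 2-fold minimum, 347 rose and 387 fell. With 1 array left out, the number that rose ranged from 261 to 699 and the number that fell from 224 to 1318. Requiring 2 arrays per gene and the median over spots changed no count, since no value is missing and nearly all genes have 2 spots. Of the 87 genes that the naming rule picked, none that had passed turned its direction in any setting. Among those that had not passed, AFT1, ARR1, CBF1 and MSN2 changed sign in at least 1 setting without passing there. In all, 22 lost their call without replicate 1, 13 without replicate 3 and 5 with a dye effect in the fit. A call was gained by 5 with centring within runs, 2 with centring, 2 with scaling, 3 without replicate 2 and 1 without replicate 3.

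Centring, scaling and centring within runs changed the call of 0 of the 25 lists. With 1 array left out, the adjusted p ranged from 0.0126 to 0.0845 for a-cell genes, 0.0357 to 0.0601 for the cell cycle, 0.00211 to 0.133 for meiosis and 0.00211 to 0.0603 for the respiratory chain. Meiosis had 0.0665 with a dye effect in the fit. On ranks, arsenic detoxification had 0.124 and glycolysis 0.0309. With an estimated correlation, 0 lists were higher and 0 lower, with adjusted p of 0.227 for aryl-alcohol dehydrogenases. The value was 0.296 for arsenic detoxification, sulfate assimilation, oxidative defence, proteasome, general stress, ribosomal proteins and histones, 0.321 for glutathione and Hog1 targets, 0.393 for ribosome biogenesis and 0.480 for heat shock. It was 0.607 for iron, amino acids, polymerases, cell cycle, ergosterol, respiratory chain and a-cell genes, and 0.671 for meiosis. With fry, 2 lists were lower, and the calls lost had adjusted p of 0.0599 for heat shock, 0.249 for iron, amino acids and ergosterol, 0.101 for ribosome biogenesis, 0.205 for polymerases, 0.272 for cell cycle, 0.127 for the respiratory chain, 0.278 for a-cell genes and 0.309 for meiosis. Spearman's correlation between arrays was 0.741, 0.740 and 0.539. The cause of these shifts was not tested. Fewer arrays, and the fewer residual degrees of freedom they leave, do not alone account for the gene counts. Without replicate 2, 699 genes rose and 1318 fell, both above the 606 and 603 as deposited. With either other array left out, both counts were below 606 and 603. The prior SD of the fit was 0.503 as deposited and 0.332 with each array centred, so offsets between arrays widened it. Whether the offset of replicate 2 set the counts with an array left out was not tested. Channel intensities were not analysed here, so what signal over background limits is unknown.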

Other observations

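The gene groups, the tests of the trend and the constant on replicate 2, the tests of dye bias and centring for ribosomal protein genes, the comparison of close with distant neighbours and that of PDC6 with PDC1 were chosen after the results were seen. The p-values of the 7 groups are adjusted over these groups alone, and with fry none passed (adjusted p from 0.0609 to 0.103). Of 19 aminoacyl-tRNA synthetase genes, 14 fell and 0 rose, among them CDC60 (-1.50 ± 0.27) and KRS1 (-1.33 ± 0.37), with a median of -0.88 (camera adjusted p = 2.92e-06, and adjusted p = 0.357 with an estimated correlation). Without replicate 1, 2 of them fell, and without replicate 3, 4 did. Of 10 genes of fatty acid synthesis and desaturation, 6 fell and 0 rose, with a median of -1.03 (adjusted p = 6.41e-05, and adjusted p = 0.357 with an estimated correlation), led by OLE1 (-2.30 ± 0.42), FAS1 (-2.10 ± 0.14) and FAA4 (-1.89 ± 0.36), and without replicate 2, 7 fell and 1 rose. Of 23 nucleotide synthesis genes, 10 fell and 2 rose, with a median of -0.28 (adjusted p = 0.00116, and adjusted p = 0.405 with an estimated correlation). URA1 (-2.52 ± 0.60), URA7 (-2.20 ± 0.51) and GUA1 (-2.11 ± 0.07) fell most, and ADE17 rose by 1.77 ± 0.35. In this group 5 fell and 1 rose without replicate 1, and 10 fell and 1 rose without replicate 3.

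Of 17 vacuolar protease and autophagy genes, 5 rose and 0 fell, with a median of 0.46 (adjusted p = 0.000252, and adjusted p = 0.405 with an estimated correlation). They included the vacuolar aminopeptidase APE1 (2.75 ± 0.25), the proteinase PRB1 (2.30 ± 0.41) and ATG8, of the autophagosome membrane (1.68 ± 0.44), and 3 of the group rose without replicate 1. Of 14 genes of ubiquitin conjugation and the Cdc48 pathway, 6 rose, UBC5 (2.52 ± 0.73) and DDI1 (2.19 ± 0.56) most, and UFD2 fell (-1.17 ± 0.59), with a median of 0.70 (adjusted p = 0.000785, and adjusted p = 0.405 with an estimated correlation). None of this group fell without replicate 1 or without replicate 3. Of 18 genes of thiamine and pyridoxine synthesis, 8 rose, THI74 (2.76 ± 0.35) and SNZ1 (2.64 ± 0.18) most, and THI4 fell (-0.86 ± 0.78), with a median of 0.46 (adjusted p = 0.000502, and adjusted p = 0.357 with an estimated correlation). The numbers that rose and fell in it were 5 and 0 without replicate 1, 8 and 2 without replicate 2, and 6 and 0 without replicate 3. Of 12 genes of the tricarboxylic acid cycle, 4 rose and 0 fell, with a median of 0.43 (adjusted p = 0.0423, adjusted p = 0.0502 over all 32 lists, which does not pass, and adjusted p = 0.424 with an estimated correlation), among them MDH1 (1.11) and CIT1 (1.02). Of 959 spot pairs without a gene symbol, 80 were higher and 46 lower at the same threshold. Spots 3875 and 3876 had the highest ratio (4.34 ± 0.16), and spots 10491 and 10492 the lowest (-2.35 ± 0.25).

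Exchanging the channels on 1 array makes 3 other sign patterns beside the real one, which called 1209 genes as deposited. The highest count among the others was 0, and 1 of 4 patterns is too large a share to reach 0.05. Replicate 3 had also been turned to correlate positively with the others, so a low count with its channels exchanged was built in. No PDC1 to PDC6 exchange, as a hypothesis of isoenzymes poorer in sulfur, was seen: the highest difference PDC6 minus PDC1 on any array was 0.24, against a minimum of 1 that was set after the results were seen. The files do not show whether the spots of PDC1 and PDC6 share hybridisation, which would bring the difference near 0, so an exchange is not excluded.

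On replicate 3, the array with exchanged dyes, the median of ribosomal protein genes was -1.87 once turned. That array was turned because it correlated negatively with the others, so the sign of this median was nearly set by the turning. If all columns hold Cy5 over Cy3, the deposited ratios of these genes changed sign with the dyes, which argues against dye bias. The sources do not state this, so dye bias is not excluded. The fall held in the 17 genes without a paralog, of which 16 fell and whose upper quartile was -1.52. This argues against hybridisation shared between paralogs as its source. The medians over all spots, -0.07, 0.54 and -0.12 once replicate 3 was turned, were small beside the fall, which argues against the uncentred scale. Centring therefore had to leave the fall in place and adds no separate test, and the highest of the 3 centred list medians was -1.73. A response of these genes to the arsenite treatment, the difference the labels name, may underlie the fall. This is a hypothesis found and tested on the same data, and it rests on the turning of replicate 3. A slower growth of the treated cells stays open, with lower medians also for ribosome biogenesis (-1.16), histones (-0.97) and the cell cycle (-0.29), and RNA quality was not tested.

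The ratios of replicate 2 exceeded the mean of the other arrays by a median of 0.63. The gap followed the spot number over 48 runs (Spearman's rho = -0.943, permutation p = 0.0001, the smallest that 10000 permutations give), from 1.07 in 1 run to -0.11 in another, and it holds opposite trends, since the run medians fell along the spot numbers on replicate 2 (rho = -0.853) and rose on replicates 1 (0.511) and 3 (0.619). A constant added to every ratio is argued against by the SD of the run gaps, 0.305, where randomly assigned spots gave at most 0.0588 in 1000 draws. Trends along the spot numbers left in the deposited ratios of all 3 arrays, steepest on replicate 2, may thus account for part of the offset, as a hypothesis. The residual SD was 0.369 with each array centred and 0.323 with centring within runs. Both values have the offset already removed, so they do not show how much of it the trends explain. No biological explanation was tested, since the labels give no difference between the replicates, and the share of the offset that is uniform stays open.

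Neighbouring genes changed alike: over 5056 adjacent pairs the ratios correlated with r = 0.149, where the highest of the permuted orders gave 0.0546. Without the ribosomal protein and biogenesis lists r was 0.112 (highest permuted 0.0534), which argues against these clusters as the whole source. Divergent pairs lay only 0.0471 above the others (one-sided permutation p = 0.0768), and convergent pairs, which share no upstream region, had r = 0.178, so a shared upstream region is not the whole source either. Pairs at least 1000 spot numbers apart had r = 0.0469, for which the permuted range decides nothing because it reaches 0.168, above the r of all pairs, but closer pairs had r = 0.166, a difference of 0.119 (two-sided permutation p = 0.0053). Closeness in spot number may account for part of the likeness, although centring within runs left r at 0.145. Spot numbers need not reflect positions on the array, so physical closeness was not tested. A local change in transcription by arsenite stays open, because chromosomal neighbours mostly had nearby spot numbers (median distance 544 spots).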
